A study of Homo sapiens with 18 samples.

How the data were processed

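Gene expression was measured on Illumina BeadArrays in 18 samples of the human melanoma line SK-MEL28, which carries BRAF V600E. Per the labels, the samples come from 3 experiments, each run on a slide of its own with 6 arrays. Each experiment holds a parental line and 2 clones, and each of these 9 lines has 1 untreated array and 1 array after 24 h of inhibitor. The inhibitors were 100 nM dabrafenib, a BRAF inhibitor, with clones BR6 and BR8; 100 nM dabrafenib plus 5 nM trametinib, a MEK inhibitor, with clones CR401 and CR201; and 10 nM trametinib with clones MR201 and MR105. The labels call the cells of the dabrafenib experiment SK-Mel28 and those of the other 2 experiments SK-Mel28#8. Whether these are different sublines is not given in the sources used here. If they are, the parental line differs between the dabrafenib experiment and the others, in the pooled parental arrays and in each comparison of the BR clones with the other sets. They expand none of the codes BR, CR and MR, and whether the clones were kept on inhibitor before the untreated arrays were made is not given in the sources used here. The labels do not say either whether the parental cultures were started independently, so the p-values measure only the spread between these samples.

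The authors deposited, per the file headers, the average bead signal of each of 47231 probes on each array as an unnormalized intensity. The deposited table also gives, per the file headers, a detection p-value for each probe on each array. GenomeStudio 2011.1 is named in the submitters' processing notes, and the labels' protocol describes biotin-labelled cRNA. A second deposited table holds processed intensity values of the same arrays, whose processing the labels do not state. Its values lie on a linear scale, fall as low as -25.3 and so were background-subtracted, and have nearly equal medians on all arrays. The column medians ran from 12.23 to 12.25. The rank correlation with the unnormalized column of the same sample was 1, against at most 0.916 with another sample's column, and the genes were not centred. The background estimate and the normalization used for that table remain unknown.

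The unnormalized intensities were read with limma 3.58.1 in R 4.3.3. They were background-corrected by normexp with negative-control parameters inferred from the detection p-values, quantile normalized with an offset of 16 and put on the log2 scale (neqc). A probe was kept when its detection p-value was under 0.01 on at least 2 of the 18 arrays, which left 20802 probes, 10758 of them detected on every array. Probe symbols come from the deposited table and were updated through a gene table of assembly GCF_000001405.40 (GRCh38.p14), which was used for names only. Of all probes, 27036 carried a current symbol, 4626 were updated through a synonym, 12299 kept the file's symbol and 3270 had none. The kept probes with a symbol numbered 19659 and represented 14873 genes. A gene with several probes is represented by the kept probe with the highest mean over all arrays.

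The number of arrays limits the precision of every value. Probes detected per array ranged from 14147 to 17735 and the mean unnormalized intensity from 309.5 to 561.1. The treated parental arrays had 0.797, 0.859 and 0.755 times the mean unnormalized intensity of their untreated partners in the dabrafenib, combination and trametinib experiments, against 0.935 to 1.029 in the clones. Pearson r between 2 arrays across genes ranged from 0.8204 to 0.9864, and no pair of arrays held identical values. The first principal component held 40.3% of the variance and the second 22.2%.

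All tests across probes used lmFit and eBayes of limma, two-sided, with Benjamini-Hochberg adjustment over the kept probes and a threshold of 0.05. The parental response, the clone response and their difference (inhibitor minus untreated over 3 parental and 6 clone pairs, and clone minus parental response) came from 1 fit to all 18 arrays with the line as a block. The responses of the BR, CR and MR clones and their pairwise differences came from a second fit of the same kind. The untreated difference (6 untreated clones minus 3 untreated parental arrays) and the on-drug difference (the same on inhibitor) used 9 arrays each with the experiment as a block. The BR, CR and MR clones were also compared separately with the 3 untreated parental arrays, without a block. Slide and experiment coincide, so both blocks take up the slide, and values within each slide are given beside the pooled ones. The pairing of arrays within a line was checked: the 2 arrays of a line deviated from their group means together in all 9 lines (r across genes from 0.63 to 0.88). The pairing comes from the line named in the labels.

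Genes named in the text follow a rule. For each of the 5 main comparisons, it takes the 6 largest rises and the 6 largest falls in log2 among genes past the threshold with the same sign in every line. For the response difference, no clone value may lie inside the parental range. Added to these are a fixed panel of 32 genes and, as examples of a gene list, the 3 members with the lowest p in the list's direction. Values per gene are means over lines with the SD between lines. Where every array of the dimmer group had a detection p-value of 0.01 or more for a probe, only a bound exists, and the text then gives "at least N-fold". That bound sets the mean of the brighter group against the mean of, per array of the dimmer group, the higher of the lowest signal of any detected probe and the probe's own signal.

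Of 26 gene lists, 21 describe biology and 5 are markers of other cell types (keratinocytes, fibroblasts, lymphocytes, macrophages and endothelium). Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each with Benjamini-Hochberg adjustment over the lists of a comparison. The p of fry tests whether the genes of a list move on balance one way, and its mixed p whether they change in either direction; neither compares the list with other genes. None of the 68 list calls made with the preset correlation over the 5 main comparisons holds with an estimated correlation. For each list, the mean response per line was also compared between the 6 clones and the 3 parental lines by an exact two-sided permutation test over 84 arrangements (smallest possible p 0.0119), and over the 27 arrangements that exchange lines only within an experiment (smallest possible p 0.037). The clone responses alone were set against 0 by an exact two-sided sign-flip test over 64 arrangements (smallest possible p 0.0312).

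The fits, tests, lists, panel, naming rule and most alternatives were fixed before the data were examined. Alternatives covered the background correction, the scaling (median in place of quantile), the deposited value table (values under 16 set to 16), the offset (100), the filter on dim probes, robust and trended eBayes, array weights, the block, a change of at least 1 in log2, the probe rule, the arrays in a fit, the control arrays and leaving out each line in turn. Leaving out the whole dabrafenib experiment, exchanging lines only within an experiment, and the lower limit set for the value table were chosen after seeing the data. The closing section gives their effect.

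The calls of limma were tested on simulated log2 values of 14873 genes, of which 50 were changed at each of 4 sizes, and camera at the preset correlation and fry for the clone response. The normalization, the fold bounds, camera at an estimated correlation and the exact tests were not tested this way. At log2 changes of 0.5, 1, 1.5 and 2, the calls recovered 16%, 90%, 100% and 100% for the parental response, 44%, 98%, 100% and 100% for the clone response, and 6%, 66%, 96% and 100% for their difference. The untreated difference gave 20%, 90%, 100% and 100%, and the on-drug difference 22%, 94%, 100% and 100%. At a log2 change of 1, recovery was 38%, 48% and 44% for the BR, CR and MR responses, 20%, 4% and 16% for CR minus BR, MR minus BR and MR minus CR, and 10%, 2% and 6% for the untreated BR, CR and MR clones. At most 10 unchanged genes were called in any comparison, and no call had the wrong direction. For the clone response, camera and fry each called 10 of 10 lists of 30 genes changed by 0.5 and 0 of 90 unchanged lists, which says nothing of correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with numpy 2.4.6.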

Results

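Expression was measured in 18 samples of SK-MEL28 melanoma cells, which carry BRAF V600E and so depend on the MAPK pathway through RAF, MEK and ERK. The samples fall into 9 lines, each with 1 untreated array and 1 array after 24 h of inhibitor. The 3 parental lines belong to 3 experiments, run with 100 nM dabrafenib, with 100 nM dabrafenib plus 5 nM trametinib, and with 10 nM trametinib. Each experiment also held 2 clones: BR6 and BR8 with dabrafenib, CR401 and CR201 with the combination, and MR201 and MR105 with trametinib. The series title speaks of cells that acquired resistance to BRAF or MEK inhibitors and of continued inhibition after that point. The number of arrays limits the precision of each value.

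In parental cells, 24 h of inhibitor lowered the genes that MAPK signalling switches on and the genes of cell division, and raised genes of pigmentation and of mitochondrial respiration. This comparison addresses what the inhibitors do in cells that were not selected for resistance. DUSP6, an ERK phosphatase induced by ERK itself, changed by -4.32 ± 1.52 (SD, n = 3) in log2 (adjusted p = 4.57e-05, lower in 3 of 3 lines). SPRY2, a feedback inhibitor of the pathway, changed by -4.28 ± 1.42 (SD, n = 3; adjusted p = 5.5e-05). Its relative SPRY4 fell at least 9.95-fold (adjusted p = 1.52e-05), the transcription factor ETV4 at least 14-fold (adjusted p = 2.86e-05) and the AP-1 member FOSL1 at least 10.4-fold (adjusted p = 1.74e-05). MYC changed by -3.1 ± 1.24 (SD, n = 3; adjusted p = 2.9e-05) and cyclin D1 (CCND1) by -2.32 ± 0.19 (SD, n = 3; adjusted p = 2.01e-05), both in 3 of 3 lines. The other falls in the panel, each in 3 of 3 lines, were ETV5 (-3.19), DUSP4 (-1.99, with another probe that did not pass), EGR1 (-1.83), CCNB1 (-1.73), MKI67 (at least 1.43-fold), MCL1 (-1.07, from -2.24, -0.67 and -0.3 in the dabrafenib, combination and trametinib experiments), CDKN1A (-0.92), PHLDA1 (-0.82), E2F1 (-0.65) and MAP2K1 (-0.54).

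The largest falls by the naming rule also included UCN2, a peptide hormone gene, at -6.76 ± 1.52 (SD, n = 3; adjusted p = 4.9e-06). The chemokine CXCL8 changed by -4.58 ± 0.22 (SD, n = 3; adjusted p = 4.66e-06) and CPN1, a carboxypeptidase subunit, by -4.23 ± 0.29 (SD, n = 3; adjusted p = 3.66e-05). Among the largest rises, ANGPTL7, a secreted angiopoietin-like protein, rose at least 19.6-fold (adjusted p = 0.000796). The potassium channel KCNJ13 rose at least 9.1-fold (adjusted p = 4.7e-06) and the myosin light chain kinase MYLK at least 7.16-fold (adjusted p = 2.9e-05). DIPK1C rose by 4.03 ± 0.41, PRUNE2 by 3.94 ± 0.58 and CITED1 by 3.73 ± 0.25 (SD, n = 3; adjusted p = 1.64e-05, 1.43e-05 and 6.2e-06), each in 3 of 3 lines.

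In the MAPK output list, 27 of 36 measured genes fell and 9 did not pass (28 fell adjusted over the list alone), with a mean of -1.93 ± 0.072 (SD, n = 3) over the lines. The list's members with the lowest p were CXCL8 (-4.58), the adaptor gene SH2B3 (-3.22) and PPAT (-1.81). Camera gave the list an adjusted p of 6.34e-14, which became adjusted p = 0.092 with an estimated correlation. All 43 measured G1/S genes fell (43 adjusted over the list alone, adjusted p = 6.31e-23, and adjusted p = 0.113 with an estimated correlation), among them UHRF1 (-3.41), the ribonucleotide reductase subunit RRM2 (-3.45) and CDCA7 (-2.36). Of 54 measured G2/M genes, 52 fell (52 adjusted over the list alone, adjusted p = 4.73e-26, and adjusted p = 0.169 with an estimated correlation), with CKAP2L at -2.36 and the centromere histone CENPA at -2.23. Genes of the nucleolus and ribosome biogenesis fell in 30 of 35 cases (32 adjusted over the list alone, adjusted p = 1.87e-17, and adjusted p = 0.092 with an estimated correlation). Among them were NOLC1 at -2.67, RRS1 at -2.2 and DKC1 at -1.95. Of 14 heat shock genes, 11 fell and 1 rose (12 and 1 adjusted over the list alone, adjusted p = 1.04e-05, and adjusted p = 0.07 with an estimated correlation). HSPH1 changed by -1.46, and the near-identical copies HSPA1A and HSPA1B, which a probe may not tell apart, by -1.49 and -1.6.

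Pigmentation genes and targets of MITF, the master regulator of melanocytes, rose in 19 of 31 cases and fell in 2 (21 and 2 adjusted over the list alone, adjusted p = 3.52e-07, and adjusted p = 0.169 with an estimated correlation). TFAP2A rose by 2.18 ± 0.04, TBX2 by 1.52 ± 0.21 and the melanocyte antigen MLANA by 1.29 ± 0.13 (SD, n = 3), and tyrosinase (TYR) rose by 0.75, while MITF itself (0.55) and PMEL (0.31) did not pass. In the oxidative phosphorylation list, 19 of 37 genes rose and 1 fell (21 and 1 adjusted over the list alone, adjusted p = 1.38e-05, and adjusted p = 0.07 with an estimated correlation). They included PPARGC1A, a coactivator of mitochondrial genes, at 1.46 ± 0.37 (SD, n = 3). Lysosomal genes rose in 15 of 27 cases and fell in 1 (15 and 2 adjusted over the list alone, adjusted p = 2.25e-05, and adjusted p = 0.232 with an estimated correlation), with CTSK at 1.69. Cholesterol biosynthesis genes rose in 12 of 28 cases and fell in 1 (12 and 1 adjusted over the list alone, adjusted p = 0.00158, and adjusted p = 0.284 with an estimated correlation). Neural crest and glial genes rose in 7 of 15 cases and fell in 1 (7 and 1 adjusted over the list alone, adjusted p = 0.034, and adjusted p = 0.184 with an estimated correlation), with L1CAM at 1.35.

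The lists of CDK inhibitors and p53 targets, the BCL2 family, immediate early genes, receptor tyrosine kinases and reference genes were not called by camera. CDK inhibitors and p53 targets rose in 11 cases and fell in 7 of 22 (adjusted p = 0.148; 11 and 7 adjusted over the list alone), with TP53INP1 at 3.29, CDKN2C at 2.6 and CDKN1B at 0.98 against CDKN1A at -0.92. In the BCL2 family, 5 rose and 4 fell of 15 (adjusted p = 0.882; 5 and 4 adjusted over the list alone); BCL2 changed by -1.8 and BID by -1.27, and the list's mean (-0.1675) and median (0.051) differ in sign. The pro-apoptotic gene BCL2L11 stood at 0.23 and did not pass. Immediate early genes fell in 8 cases and rose in 1 of 18 (adjusted p = 0.0606; 8 and 1 adjusted over the list alone), with DUSP1 at -1.08 and KLF4 at -0.81. AXL, EGFR and PDGFRB were not above background on any parental array and give no fold here, and of the panel's other receptors ERBB3 rose by 0.89 ± 0.18 (SD, n = 3; adjusted p = 0.0025). In the list of receptor tyrosine kinases and their ligands, 5 rose and 4 fell of 26 (adjusted p = 0.948; 5 and 4 adjusted over the list alone). The 20 reference genes held 2 rises and 6 falls (adjusted p = 0.361; 2 and 6 adjusted over the list alone), HPRT1 at -1.33 among the falls, and their mean (-0.1776) and median (0.0202) differ in sign.

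The parental response called 7376 of 20802 probes with limma, 3657 higher and 3719 lower, and 2337 of them changed at least 2-fold. Of 5578 genes called, 5532 had the same sign in all 3 lines, and 99.4%, 99.9% and 99.9% kept the pooled direction within the slide of the dabrafenib, combination and trametinib experiment. Without the line as a block, 1635 probes were called. Of 31 called genes named above as largest or panel, 25 kept their call when any line was left out; those that lost it were CDKN1A, E2F1, MAP2K1, MCL1, PHLDA1 and TYR. Without the parental line of the dabrafenib experiment, the adjusted p was 0.0741 for E2F1 and 0.0863 for MCL1, which then stood at -0.487. Without that of the combination experiment, it was 0.0758 for CDKN1A, 0.155 for E2F1, 0.0547 for MAP2K1, 0.0704 for PHLDA1 and 0.0944 for TYR, and without that of the trametinib experiment 0.0681 for MAP2K1 and 0.0507 for TYR. The call was also lost for E2F1 on the value table (0.0671) and with no filter on dim probes (0.0502), for TYR under median scaling (0.4, adjusted p = 0.175), for MCL1 with only parental arrays in the fit (0.0594), for CDKN1A (0.0529), E2F1 (0.0906) and MCL1 (0.0541) without the dabrafenib experiment, and for 12 genes without a block.

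**Figure D1:**
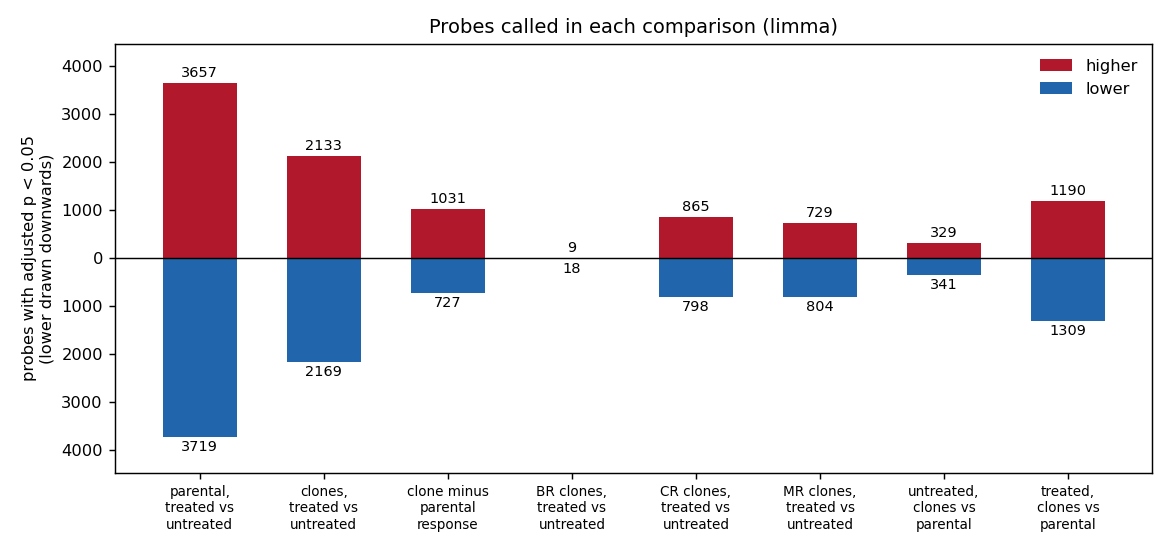
Number of probes with an adjusted p under 0.05 (limma), those higher drawn upwards and those lower downwards, for each comparison on the x axis. The parental response holds 3657 higher and 3719 lower probes, and the BR clones on dabrafenib 9 and 18.

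In the clones, inhibitor still lowered the direct readouts of the MAPK pathway, by less than in parental cells for several genes. This comparison addresses whether the pathway still responds in the clones. SPRY4 changed by -2.95 ± 0.96 (SD, n = 6; adjusted p = 0.000103), ETV4 by -2.86 ± 1.02 (SD, n = 6; adjusted p = 0.000146) and EGR1 by -2.22 ± 0.92 (SD, n = 6; adjusted p = 0.000313), each lower in 6 of 6 clones. DUSP6 changed by -2.03 ± 0.85 (SD, n = 6; adjusted p = 0.00213) and CCND1 by -1.18 ± 0.51 (SD, n = 6; adjusted p = 0.00065), each in 6 of 6 clones. ETV5 changed by -2.59 ± 1.78 (SD, n = 6; adjusted p = 0.00317) and was lower in 5 of 6 clones, with BR6 at 0.05. MYC stood at -0.52 ± 0.23 (SD, n = 6) and did not pass (adjusted p = 0.13).

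The largest falls in the clones by the naming rule included IL1B, LIF, CCL20 and CPN1. The cytokine IL1B changed by -2.84 ± 0.7, LIF by -2.71 ± 1.05 and the chemokine CCL20 by -2.66 ± 0.91 (SD, n = 6; adjusted p = 0.000126, 0.000307 and 0.00011), and CPN1 by -2.67 ± 1.19 (SD, n = 6; adjusted p = 0.000351), each in 6 of 6 clones. Among the rises, ANGPTL7 rose at least 9.42-fold (adjusted p = 0.00121) and CCDC85A at least 3.25-fold (adjusted p = 0.000461). CRISPLD2 rose by 2.67 ± 1.35, PRUNE2 by 2.45 ± 0.83, the small heat shock protein HSPB3 by 2.42 ± 1.34 and MYLK by 2.2 ± 1.01 (SD, n = 6; adjusted p = 0.000804, 0.000146, 0.00109 and 0.000533), each in 6 of 6 clones. The receptor PDGFRB rose at least 1.11-fold (adjusted p = 0.00516), in 5 of 6 clones. Of the rest of the panel, DUSP4 (-1.93, with another probe that did not pass), FOSL1 (-1.69), SPRY2 (-1.51), MCL1 (-0.96), PHLDA1 (-0.94), CDKN1A (-0.85), MKI67 (-0.66, with BR6 at 0.66), CCNB1 (-0.52) and MAP2K1 (-0.45) fell. MLANA (1.03), PPARGC1A (0.91), CDKN1B (0.38, with another probe that did not pass) and PMEL (0.38) rose.

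Of 36 MAPK output genes, 28 fell in the clones (30 adjusted over the list alone, adjusted p = 6.28e-20, and adjusted p = 0.139 with an estimated correlation). Among them were SH2B3 at -2.13 and the urokinase receptor PLAUR at -1.36. The list's mean response was -1.262 ± 0.359 (SD, n = 6), lower in 6 of 6 clones, by an exact two-sided sign-flip test p = 0.0312, the smallest possible, and 0.0579 after adjustment over the 26 lists. No list passed that adjusted sign-flip test. Immediate early genes fell in 8 cases and rose in 3 of 18 (9 and 3 adjusted over the list alone, adjusted p = 0.00253, and adjusted p = 0.158 with an estimated correlation), with KLF4 at -1.07 and FOSB at -1.34 (lower in 5 of 6 clones). Of 43 G1/S genes, 31 fell (35 adjusted over the list alone, adjusted p = 1.46e-14, and adjusted p = 0.2 with an estimated correlation). Among them was RRM2 at -1.2. Of 54 G2/M genes, 29 fell (37 adjusted over the list alone, adjusted p = 9.99e-15, and adjusted p = 0.271 with an estimated correlation). Nucleolar and ribosome biogenesis genes fell in 28 of 35 cases (29 adjusted over the list alone, adjusted p = 2.46e-14, and adjusted p = 0.158 with an estimated correlation).

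Pigmentation genes rose in 10 of 31 cases and fell in 2 (11 and 2 adjusted over the list alone, adjusted p = 0.00462, and adjusted p = 0.342 with an estimated correlation), with the melanin enzyme DCT at 1.25 ± 0.3, TFAP2A at 1.2 ± 0.33 and MLANA at 1.03 ± 0.17 (SD, n = 6). Oxidative phosphorylation genes rose in 6 of 37 cases and fell in 2 (6 and 2 adjusted over the list alone, adjusted p = 0.0154, and adjusted p = 0.2 with an estimated correlation). Lysosomal genes rose in 10 of 27 cases and fell in 2 (11 and 2 adjusted over the list alone, adjusted p = 0.00639, and adjusted p = 0.343 with an estimated correlation). Cholesterol biosynthesis genes rose in 8 of 28 cases (8 adjusted over the list alone, adjusted p = 0.000865, and adjusted p = 0.271 with an estimated correlation). Neural crest and glial genes rose in 5 of 15 cases and fell in 1 (6 and 1 adjusted over the list alone, adjusted p = 0.0344, and adjusted p = 0.2 with an estimated correlation). Heat shock genes fell in 6 cases and rose in 2 of 14 (9 and 2 adjusted over the list alone, adjusted p = 0.0178, and adjusted p = 0.2 with an estimated correlation), with a list mean of 0.047 in MR201. Markers of fibroblasts moved with these groups: COL1A1 (1.39), LUM (0.55) and PDGFRB rose and 1 marker fell of 7 (4 and 1 adjusted over the list alone, adjusted p = 0.0344, and adjusted p = 0.306 with an estimated correlation), with a mean of -0.041 in BR6. Keratinocyte markers stood at 0.385 ± 0.2 (SD, n = 6), higher in 6 of 6 clones with 2 of 6 genes called (2 adjusted over the list alone); fry called them (adjusted p = 0.00791) and camera did not (adjusted p = 0.286).

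The clone response called 4302 probes with limma, 2133 higher and 2169 lower, and 397 of them changed at least 2-fold. Of 3289 genes called, 2668 had the same sign in all 6 clones. Within the slides of the dabrafenib, combination and trametinib experiments, 99.1%, 100% and 99.9% kept the pooled direction, with median sizes 0.72, 1.16 and 1.12 times the pooled ones. Without CR401, 2662 probes were called, without MR105 2849, and without the line as a block 152, where the pigmentation list was not called (adjusted p = 0.0746). Of 30 called genes named above as largest or panel, 26 kept their call when any line was left out. The others were CCNB1 (adjusted p = 0.0655 without CR401, 0.0562 without MR105), CDKN1B (0.102, 0.107, 0.0632 and 0.0523 without CR401, CR201, MR201 and MR105) and PMEL (0.102, 0.0985 and 0.0572 without CR401, CR201 and MR105). MKI67 had an adjusted p of 0.0744, 0.102, 0.0932, 0.0842 and 0.12 without BR8, CR401, CR201, MR201 and MR105, and 0.0504 without the parental line of the combination experiment. The call was also lost on the value table for CDKN1B (0.0501), MCL1 (0.0588) and MKI67 (0.0683), under median scaling for CDKN1B (0.0869) and PMEL (0.0587), at an offset of 100 for MKI67 (0.0544), with no filter on dim probes for CDKN1B (0.0528) and MKI67 (0.0966), with only clone arrays for MKI67 (0.0605) and PMEL (0.0545), and without a block for 21 genes.

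**Figure D2:**
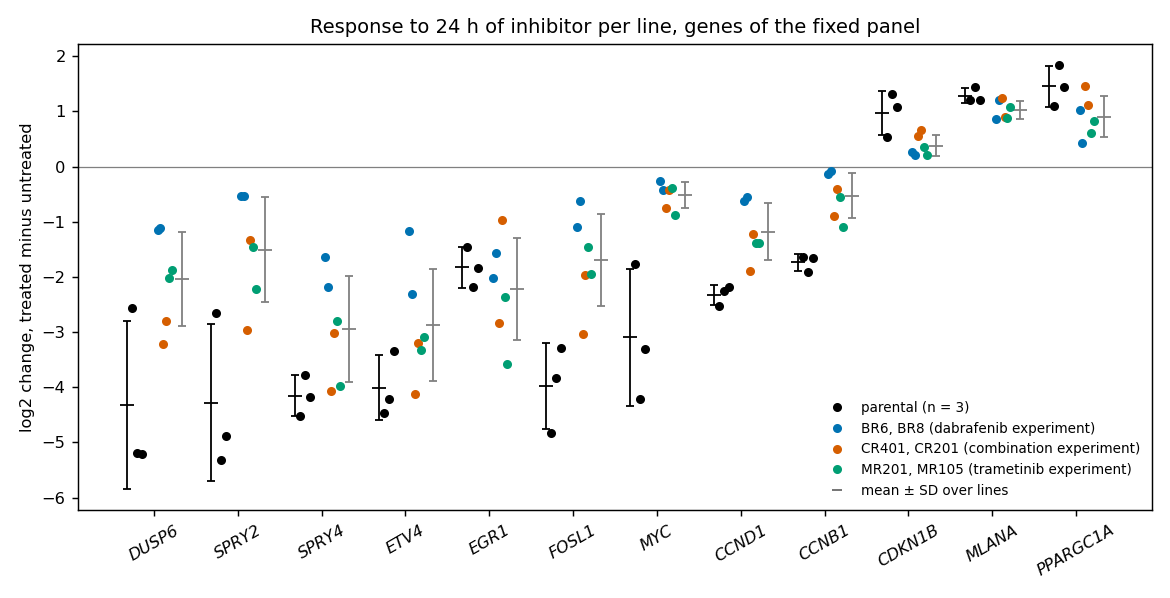
Change in log2 (inhibitor minus untreated) of panel genes in each line, with a point per line, the parental lines set beside the BR, CR and MR clones. DUSP6 lies at -2.57, -5.19 and -5.21 in the 3 parental lines and between -1.12 and -3.22 in the 6 clones.

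The clones' response was smaller than the parental one across genes (slope of clone on parental 0.4), cell division and growth genes included. This comparison addresses how far the clones escape the inhibitors. MYC fell by 3.1 in parental cells and stood at -0.52 in the clones, a difference of 2.57 (SE 0.39, adjusted p = 0.00345). UHRF1, which maintains DNA methylation in S phase, differed by 2.78 (SE 0.22, adjusted p = 0.000187, with another probe that did not pass), and the cell cycle factor E2F2 by 2.75 (SE 0.29, adjusted p = 0.000551). UCN2 differed by 4.37 (SE 0.59, adjusted p = 0.002). HSPB3 passed as well (adjusted p = 0.0265), but it rose in the clones and was above background on no parental array, so its response was not the smaller one. In the other direction, AIF1L (-3.24), the anthrax toxin receptor ANTXR2 (-2.54), CITED1 (-2.32), the TGF-beta receptor TGFBR2 (-2.3) and SOCS6 (-2.28) rose less in the clones or not at all (adjusted p = 0.000521, 0.0028, 0.00301, 0.00285 and 0.0141). KCNJ13 passed too (adjusted p = 0.000521) and gives no size, since it was above background on no untreated array.

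Among genes of the MAPK pathway's own output, the difference passed for some and not for others, which were not tested against each other. SPRY2 (2.78, adjusted p = 0.0171), DUSP6 (2.29, adjusted p = 0.0352, with another probe that did not pass) and CCND1 (1.15, adjusted p = 0.0255) fell less in the clones. So did FOSL1 (adjusted p = 0.0116), at -1.69 in the clones against a parental fall of at least 10.4-fold. For DUSP4 (0.05, adjusted p = 0.963), EGR1 (-0.39, adjusted p = 0.651), PHLDA1 (-0.12, adjusted p = 0.833) and ETV5 (0.61, adjusted p = 0.708) the difference did not pass. For ETV4 and SPRY4 it stays unknown (adjusted p = 0.189 and 0.133), since the treated parental arrays lay at background and their falls are bounds. Over the list, 10 of 36 genes were higher in the difference and 1 lower (15 and 3 adjusted over the list alone, adjusted p = 0.000119, and adjusted p = 0.276 with an estimated correlation). Its mean response in the clones was 65.4% of that in parental cells, a difference of 0.668 that did not pass the exact two-sided permutation test after adjustment (p = 0.0357, adjusted 0.0714).

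The same exact test passed for 10 of the 26 lists, each with its smallest possible p of 0.0119 and an adjusted p of 0.0309. That test exchanges lines across experiments and sets no list against other genes. With lines exchanged only within an experiment, chosen after seeing the data, 27 arrangements remain, the smallest possible p is 0.037, the 10 lists were at it, and none of the 26 passed after adjustment (adjusted p = 0.0741). The mean response of G1/S genes was -1.561 ± 0.043 (SD, n = 3) in parental lines and -0.491 ± 0.27 (SD, n = 6) in clones, or 31.5% in size. That of G2/M genes was -1.527 ± 0.107 (SD, n = 3) and -0.465 ± 0.325 (SD, n = 6), or 30.4%, and that of nucleolar genes -1.255 ± 0.032 (SD, n = 3) and -0.501 ± 0.183 (SD, n = 6), or 39.9%. That of heat shock genes was -0.773 ± 0.059 (SD, n = 3) and -0.06 ± 0.063 (SD, n = 6), or 7.8%. The pigmentation list kept 29.1%, oxidative phosphorylation 32.2%, lysosome 33.9%, CDK inhibitors and p53 targets 17%, the AXL-associated undifferentiated state 24.6% and the reference genes 27.2% of the parental mean. For the reference genes, HPRT1 (1.03), TUBA1B (0.86) and YWHAZ (0.7) were higher in the difference and 1 gene lower of 20 (5 and 2 adjusted over the list alone), the camera call did not pass (adjusted p = 0.437), and the mean (0.1293) and median (-0.0322) differ in sign.

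Gene by gene, 27 of 43 G1/S genes were higher in the difference (34 adjusted over the list alone, adjusted p = 6.14e-24, and adjusted p = 0.129 with an estimated correlation), with DTL at 2.09 and CDCA7 at 1.84. So were 37 of 54 G2/M genes (50 adjusted over the list alone, adjusted p = 3.2e-28, and adjusted p = 0.204 with an estimated correlation). Among them were CENPA at 1.67 and CKAP2L at 1.59. Nucleolar genes gave 16 of 35 (25 adjusted over the list alone, adjusted p = 3.4e-15, and adjusted p = 0.129 with an estimated correlation), with NOLC1 at 1.73. Heat shock genes gave 6 of 14 (9 adjusted over the list alone, adjusted p = 3.52e-07, and adjusted p = 0.0625 with an estimated correlation). Pigmentation genes were lower in 7 of 31 cases (13, and 1 higher, adjusted over the list alone, adjusted p = 8e-07, and adjusted p = 0.211 with an estimated correlation). Among them was MLPH at -1.3. Lysosomal genes were lower in 7 of 27 cases (10 adjusted over the list alone, adjusted p = 1.96e-05, and adjusted p = 0.218 with an estimated correlation). CDK inhibitors and p53 targets were lower in 5 of 22 cases (8, and 1 higher, adjusted over the list alone, adjusted p = 0.021, and adjusted p = 0.211 with an estimated correlation). Among them were CDKN2C at -1.72 and BTG1 at -1.64. Of 37 oxidative phosphorylation genes, 1 was lower and 1 higher (6 and 1 adjusted over the list alone, adjusted p = 3.7e-05, and adjusted p = 0.0625 with an estimated correlation). Fibroblast markers moved too, with LUM at 0.88 the called gene of 7 (3 adjusted over the list alone, adjusted p = 0.0377, and adjusted p = 0.276 with an estimated correlation).

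Across 14873 genes, which are not independent replicates, the mean clone and parental responses correlated with Pearson r = 0.739, and the slope of clone on parental was 0.4. Both responses called 2463 genes, 2439 in the same direction and 24 in opposite directions. Of these, 1183 fell in both, against 291.8 for independent lists, and 1256 rose in both, against 325.3. The response difference called 1758 probes with limma, 1031 higher and 727 lower, and of 1344 genes 1073 had a smaller change of the same sign in the clones. Within the slides of the dabrafenib, combination and trametinib experiments, 99.9%, 99.9% and 100% of these genes kept the pooled direction. The count was 1130 without BR8, 555 and 684 without the parental lines of the combination and trametinib experiments, 572 without the dabrafenib experiment and 45 without the line as a block. Of 17 called genes named here as largest or panel, 11 kept their call when any line was left out. Without the parental line of the combination experiment, the adjusted p was 0.0601 for CCNB1 (1.21 with all lines), 0.0839 for CCND1, 0.159 for DUSP6, 0.0843 for HSPB3 and 0.0966 for SPRY2. Without that of the trametinib experiment, it was 0.0698 for CCND1, 0.157 for DUSP6, 0.0783 for HSPB3, 0.061 for SOCS6 and 0.0838 for SPRY2. Without that of the dabrafenib experiment, it was 0.0838 for CCND1 and 0.0837 for HSPB3, and without BR6, BR8, MR201 or MR105 it was 0.0587, 0.0678, 0.0598 or 0.0521 for DUSP6. On the value table CCND1 (0.0521), DUSP6 (0.0555), HSPB3 (0.0709) and SOCS6 (0.102) lost the call, at an offset of 100 DUSP6 (0.0966) and FOSL1 (0.0551), and with no filter on dim probes CCND1 (0.0591), DUSP6 (0.0988), HSPB3 (0.0785) and SPRY2 (0.0556). So did DUSP6 (0.0906), HSPB3 (0.0559) and SPRY2 (0.0558) with robust eBayes, CCNB1 (0.0618), CCND1 (0.744, adjusted p = 0.131) and FOSL1 (adjusted p = 0.0868, its difference smaller by more than 1.5 times) without the dabrafenib experiment, and 14 genes without a block. Median scaling in place of quantile scaling put the median change of all probes at -0.1431 in the parental response (0.0101 with quantile scaling), at 0.1756 in the difference (-0.0054) and at -0.1898 in the untreated difference (-0.0172); it called 85.6% of the differing probes higher against 58.6% here, and no named gene or list that was called turned its direction.

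Few probes differed between the responses of the BR, CR and MR clones, by a test with low recovery at log2 changes of 1. This comparison addresses whether the regimen used in an experiment sets how its clones respond. The CR clones on the combination had 1663 probes called (865 higher, 798 lower) and the MR clones on trametinib 1533 (729 higher, 804 lower). The BR clones on dabrafenib had 27 (9 higher, 18 lower), with 2405 at an unadjusted p under 0.05, and none of the genes named by the rule was among them. In the BR clones IL1B stood at -2.62 (SE 0.51, adjusted p = 0.0847) and CXCL8 at -1.75 (SE 0.37, adjusted p = 0.103). ETV4 stood at -3.66 in the CR clones (SE 0.33, adjusted p = 0.000905) and fell to background in both treated MR clones (adjusted p = 0.00256). SPRY4 stood at -3.54 (SE 0.32, adjusted p = 0.000905) and -3.39 (SE 0.32, adjusted p = 0.00154), lower in 2 of 2 clones of each set. CXCL8 fell by 2.43 in the CR clones (SE 0.37, adjusted p = 0.00601) and by 2.58 in the MR clones (SE 0.37, adjusted p = 0.00542). The MAPK output list stood at -0.831 in BR6, -0.969 in BR8, -1.749 in CR401, -1.185 in CR201, -1.216 in MR201 and -1.619 in MR105. G2/M genes stood at 0.015 in BR6 and -0.128 in BR8 and at -0.554 to -0.723 in the CR and MR clones, and G1/S genes at -0.202 and -0.156 against -0.43 to -0.786; these list means were not tested between sets.

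Tested directly between sets with limma, CR minus BR called 0 probes (1539 at an unadjusted p under 0.05) and MR minus CR 0 (1649). MR minus BR called 2 (1760), TAGLN, for an actin-binding protein, at 3.08 (SE 0.31, adjusted p = 0.0304) and NPPB, a natriuretic peptide, at 1.97 (SE 0.22, adjusted p = 0.0427). Both were named after their values were seen. In simulated data, the tests of CR minus BR, MR minus BR and MR minus CR recovered 20%, 4% and 16% of log2 changes of 1. Of changes of 2 they recovered 92%, 94% and 82%. The low counts thus do not show that the sets respond alike in smaller changes. With 2 clones per set, these counts rest on single lines. BR had 0 probes without BR6 or without BR8, and 1 without the parental line of the combination or of the trametinib experiment. CR had 90 without CR401 and 266 without CR201, and MR had 7 without MR105 and 1018 without MR201. MR minus BR had 1 probe without the parental line of the trametinib experiment and 0 without any other line. Without the line as a block, BR, CR and MR had 2, 17 and 16 probes and MR minus BR 0.

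Before inhibitor, the clones already differed from parental cells in the lists of the AXL-associated undifferentiated state of melanoma and of pigmentation, and in single genes such as IL1B. This comparison addresses what distinguishes the clones without inhibitor on the array. IL1B was 91.9-fold higher, at 6.52 ± 1.74 (SD, n = 6; adjusted p = 0.00159), and SERPINB2, a plasminogen activator inhibitor, was higher by 7.39 ± 1.48 (SD, n = 6; adjusted p = 0.0014), each in 6 of 6 clones. The hair keratin KRT34 was at least 53.9-fold higher (adjusted p = 0.00735), BEX1 at least 48.5-fold (adjusted p = 0.00808, with another probe that did not pass), the matrix protease MMP3 at least 40.6-fold (adjusted p = 0.00857) and KRT81 at least 29.6-fold (adjusted p = 0.016), each in 6 of 6 clones. The receptor tyrosine kinase AXL was at least 13.5-fold higher (adjusted p = 0.0312, in 6 of 6 clones, with another probe that did not pass). The neurotrophin receptor NGFR was higher by 3.05 ± 0.97 (SD, n = 6; adjusted p = 0.0068), the CDK inhibitor CDKN1A by 2.45 ± 0.57 (SD, n = 6; adjusted p = 0.00357) and EGR1 by 2.28 ± 0.55 (SD, n = 6; adjusted p = 0.00357). On the lower side, the amino acid transporter SLC16A10 was at least 8.28-fold lower (adjusted p = 0.000519) and KBTBD11 at least 3.03-fold lower (adjusted p = 0.000877). PLA1A (-3.51), the melanosome gene OCA2 (-3.45), STK32A (-3.18) and TUBB4 (-2.88) were lower, each in 6 of 6 clones (adjusted p = 0.0271, 0.0235, 0.0194 and 0.0152). So were PPARGC1A (-1.8), PMEL (-1.64) and IGF1R (-0.98), with adjusted p = 0.0274, 0.0439 and 0.0227.

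The remaining panel genes did not pass. DUSP6 stood at 0.32, SPRY2 at -0.1, MYC at -0.25 and CCND1 at 0.55 in the untreated clones against parental cells (adjusted p = 0.215, 0.818, 0.359 and 0.0997). MITF stood at -1.41 ± 0.72 (SD, n = 6), lower in 6 of 6 clones, with an adjusted p of 0.0725. EGFR was at least 1.06-fold higher, in 5 of 6 clones, and did not pass either (adjusted p = 0.234).

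In the list of the AXL-associated undifferentiated state, 10 of 24 genes were higher (16 adjusted over the list alone, adjusted p = 3.92e-12, and adjusted p = 0.172 with an estimated correlation). TGFBI, a matrix protein induced by TGF-beta, stood at 4.28 ± 1.11 and CXCL8 at 3.51 ± 0.61 (SD, n = 6). The mean of the list was higher by 0.526 in BR6 and by 1.652 to 2.188 in the other clones. Matrix and TGF-beta genes were higher in 5 of 24 cases (9 adjusted over the list alone, adjusted p = 1.41e-05, and adjusted p = 0.268 with an estimated correlation), with the fibronectin receptor subunit ITGA5 at 3.49 and TIMP1 at 1.37. Receptor tyrosine kinases and ligands were higher in 4 of 26 cases and lower in 1 (6 and 4 adjusted over the list alone, adjusted p = 0.00627, and adjusted p = 0.322 with an estimated correlation). Among them were HBEGF at 1.85 and EPHA2 at least 4.57-fold higher. The fibroblast markers stood at a mean of 0.5148 beside these lists and were not called (adjusted p = 0.244; 3 higher and 1 lower of 7 adjusted over the list alone).

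Immediate early genes were higher in 6 of 18 cases (11 adjusted over the list alone, adjusted p = 5.46e-09, and adjusted p = 0.121 with an estimated correlation), with JUN at 2.77 and ATF3 at 1.19. MAPK output genes were higher in 10 of 36 cases (17, and 5 lower, adjusted over the list alone, adjusted p = 1.41e-05, and adjusted p = 0.172 with an estimated correlation), led by CXCL8, PLAUR (2.36) and EGR1. CDK inhibitors and p53 targets were higher in 4 of 22 cases and lower in 1 (8 and 2 adjusted over the list alone, adjusted p = 0.0112, and adjusted p = 0.172 with an estimated correlation). Pigmentation genes were lower in 5 of 31 cases (20 adjusted over the list alone, adjusted p = 2.35e-08, and adjusted p = 0.268 with an estimated correlation), with a mean of -0.097 in BR6 and of -0.961 to -1.567 in the other clones. G1/S genes were lower in 2 of 43 cases (12 adjusted over the list alone, adjusted p = 1.08e-09, and adjusted p = 0.206 with an estimated correlation), while 1 of 54 G2/M genes was lower and the list was not called (adjusted p = 0.324). Oxidative phosphorylation genes were lower in 2 of 37 cases (8 adjusted over the list alone, adjusted p = 3.06e-07, and adjusted p = 0.268 with an estimated correlation). Cholesterol biosynthesis genes were lower in 1 of 28 cases (1 adjusted over the list alone, adjusted p = 0.0169, and adjusted p = 0.322 with an estimated correlation), the fatty acid synthase FASN at -0.78.

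The untreated difference called 670 probes with limma, 329 higher and 341 lower, and of 518 genes 517 had the same sign in all 6 clones and 518 kept the pooled direction within each of the 3 slides. The count moved with single lines, from 40, 70 and 230 without the parental line of the trametinib, combination and dabrafenib experiment to 241, 308, 363 and 419 without MR201, MR105, BR8 and CR201, and 1468 without BR6; without the experiment as a block it was 95, and under median scaling 1747, of which 20.7% were higher against 49.1%. Of 19 called genes named here as largest or panel, SERPINB2, IL1B, SLC16A10, KBTBD11 and EGR1 kept their call when any line was left out. Without the parental line of the trametinib experiment, the other 14 had adjusted p from 0.0571 (CDKN1A) to 0.238 (PMEL). Without that of the combination experiment, 13 lost the call, with 0.18 for AXL, 0.0541 for NGFR and 0.231 for PMEL, and without that of the dabrafenib experiment 8, with 0.0623 for AXL and 0.0571 for OCA2. Without MR201, the adjusted p was 0.0808 for AXL, 0.0605 for OCA2, 0.0693 for PLA1A, 0.0958 for PMEL, 0.0663 for PPARGC1A and 0.0565 for STK32A, and without MR105 it was 0.07, 0.0545, 0.0592, 0.088, 0.0631 and 0.0516. Without BR8, it was 0.0537 for AXL and 0.0802 for PMEL; without CR401, 0.0591 for PMEL and 0.0527 for PPARGC1A; and without CR201, 0.05 for AXL and PPARGC1A and 0.0591 for PMEL. On the value table the call was lost for AXL (0.0668), OCA2, PLA1A, PMEL (0.0988), PPARGC1A, STK32A and TUBB4, and with no filter on dim probes for these (AXL 0.103, PMEL 0.118) and KRT81. It was also lost for AXL (0.102), KRT81, OCA2, PLA1A, PMEL and STK32A with robust eBayes, AXL (0.0662), IGF1R, KRT81 and PMEL at an offset of 100, IGF1R without the dabrafenib experiment (0.0825), and 8 genes without a block (AXL 0.0722).

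Set by set against the 3 untreated parental arrays, BR, CR and MR clones had 24, 91 and 75 probes called (13, 69 and 32 of them higher). IL1B was higher by 6.34, 7.93 and 5.29, SERPINB2 by 6.67, 7.92 and 7.6 and CXCL8 by 3.96, 3.23 and 3.33 in the BR, CR and MR clones (adjusted p from 0.0115 to 0.0479). HAS2, a hyaluronan synthase, was lower in each, at -2.53, -2.14 and -2.9 (adjusted p = 0.0183, 0.0324 and 0.00752), and so was CPVL (adjusted p = 0.029, 0.0355 and 0.0164), which was above background on no untreated clone. The log2 differences of CR and MR correlated across genes with r = 0.701 (covariance 0.325), where unchanged groups simulated against the same 3 controls gave 0.398 (0.0558). BR and CR gave 0.343 (0.177) against 0.4 (0.056), and BR and MR 0.119 (0.0609) against 0.399 (0.0561). Genes called in both with the same direction numbered 28, 15 and 16 for these pairs, against 0.13, 0.04 and 0.03 for independent lists; part of this excess can come from the shared controls, which were too few to divide. Without the parental line of the dabrafenib experiment, BR, CR and MR had 5445, 186 and 155 probes; without that of the combination experiment 0, 0 and 3, and without that of the trametinib experiment 0, 1 and 43. Without 1 of the clones they had 0 to 136, 0 to 287 and 2 to 180. Against their own experiment's parental array alone, they had 0, 5 and 6.

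**Figure D3:**
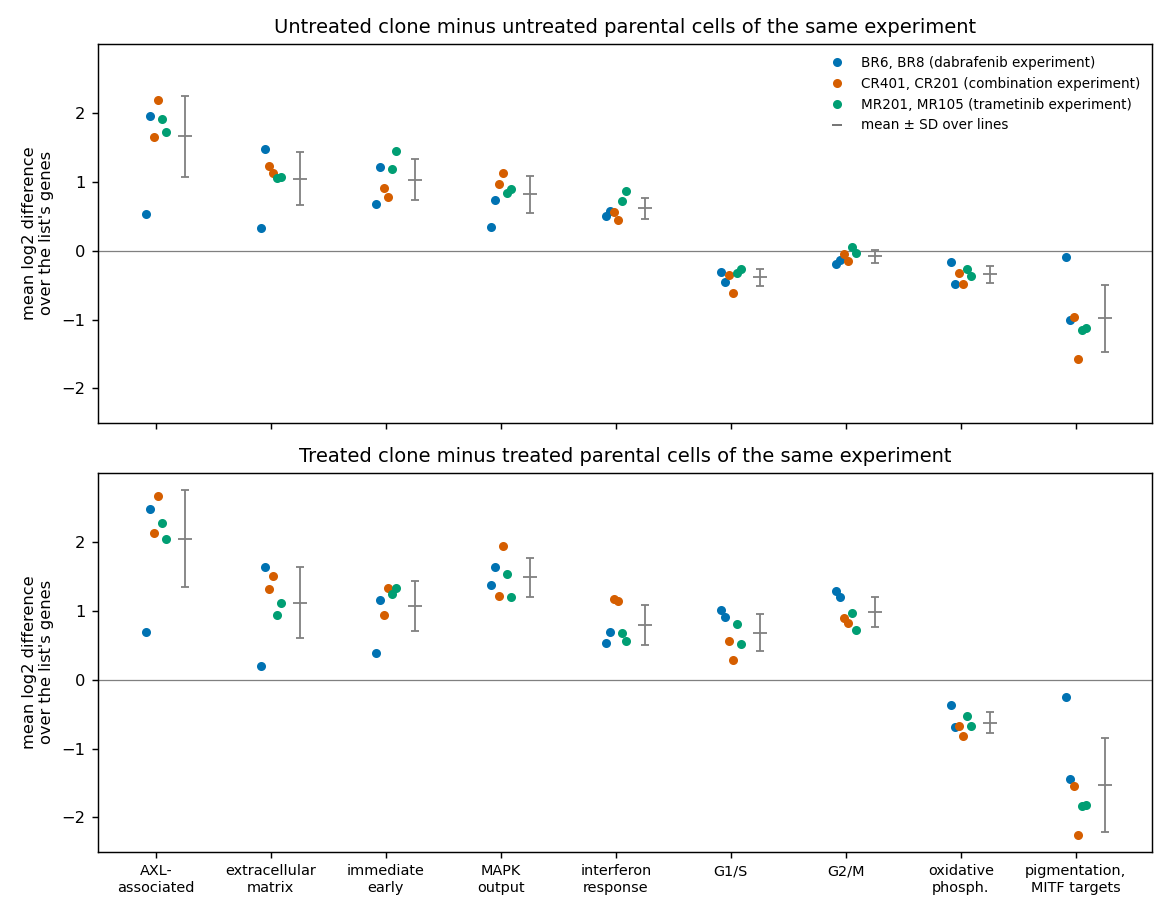
Log2 difference of each clone from the parental array of its own experiment, untreated and on inhibitor, for the means of gene lists, with a point per clone. Untreated BR6 lies at 0.526 in the list of the AXL-associated undifferentiated state, and the other 5 clones lie between 1.652 and 2.188.

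On inhibitor, the clones had higher expression of MAPK output and cell division genes than parental cells on the same inhibitor, and lower expression of pigmentation genes. This comparison addresses the state in which clones and parental cells are both exposed. CXCL8 was higher by 5.83 ± 0.69 (SD, n = 6; adjusted p = 0.000308), SPRY2 by 2.68 ± 0.54 (SD, n = 6; adjusted p = 0.00158), DUSP6 by 2.61 ± 0.71 (SD, n = 6; adjusted p = 0.00147, with another probe that did not pass) and MYC by 2.33 ± 1.08 (SD, n = 6; adjusted p = 0.00603), each in 6 of 6 clones. FOSL1 was at least 5.99-fold higher (adjusted p = 0.00404) and SPRY4 at least 1.93-fold (adjusted p = 0.023, with another probe that did not pass). CDKN1A (2.52), EGR1 (1.89), CCND1 (1.7) and CCNB1 (1.18) were higher in 6 of 6 clones (adjusted p = 0.00928, 0.016, 0.00754 and 0.0102), and CDKN1B (-1.07) lower in 6 of 6 (adjusted p = 0.0173). ETV4 (at least 1.1-fold), ETV5 (0.11) and DUSP4 (-0.15) did not pass (adjusted p = 0.714, 0.938 and 0.849).

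AXL was at least 12.4-fold higher (adjusted p = 0.0165) and NGFR higher by 3.16 ± 1.19 (SD, n = 6; adjusted p = 0.00707), each in 6 of 6 clones, and PDGFRB at least 1.07-fold higher (adjusted p = 0.0352, in 5 of 6). BEX1 was at least 89.9-fold (with another probe that did not pass), SERPINB2 at least 80.8-fold, KRT34 at least 48.7-fold, MMP3 at least 27.8-fold and KRT81 at least 20.6-fold higher (adjusted p = 0.0022, 0.00147, 0.00338, 0.0067 and 0.00926), each in 6 of 6 clones. SLC16A10 (-4.13), OCA2 (-4.07), STK32A (-3.88), DIPK1C (-3.86), HAS2 (-3.67) and CPVL (-3.38) were lower in 6 of 6 clones (adjusted p = 0.00101, 0.00676, 0.00259, 0.00158, 0.00476 and 0.000327). PPARGC1A (-2.35, adjusted p = 0.012) and PMEL (-1.57, adjusted p = 0.0255) were lower in 6 of 6 clones, while MITF (-2.05, lower in 5 of 6) and MLANA (-1.83, lower in 6 of 6) did not pass (adjusted p = 0.0642 and 0.0557).

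MAPK output genes were higher in 20 of 36 cases (24 adjusted over the list alone, adjusted p = 1.59e-12, and adjusted p = 0.125 with an estimated correlation). G2/M genes were higher in 38 of 54 cases (44 adjusted over the list alone, adjusted p = 2.7e-23, and adjusted p = 0.125 with an estimated correlation), with CKAP2L at 1.94. G1/S genes were higher in 16 of 43 cases (23 adjusted over the list alone, adjusted p = 8.17e-11, and adjusted p = 0.2 with an estimated correlation). Among them was UHRF1 at 2.71. Nucleolar genes were higher in 18 of 35 cases (23 adjusted over the list alone, adjusted p = 4.92e-12, and adjusted p = 0.125 with an estimated correlation), heat shock genes in 7 of 14 (8 adjusted over the list alone, adjusted p = 3.32e-05, and adjusted p = 0.125 with an estimated correlation), and immediate early genes in 6 of 18 (11 adjusted over the list alone, adjusted p = 0.000152, and adjusted p = 0.145 with an estimated correlation).

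The list of the AXL-associated undifferentiated state was higher in 12 of 24 cases (16 adjusted over the list alone, adjusted p = 2.57e-09, and adjusted p = 0.2 with an estimated correlation), with TGFBI at 4.05. Matrix and TGF-beta genes were higher in 7 and lower in 1 of 24 (9 and 1 adjusted over the list alone, adjusted p = 0.000314, and adjusted p = 0.301 with an estimated correlation). Among them was fibronectin (FN1) at 1.43. Receptor tyrosine kinases and ligands were higher in 5 and lower in 1 of 26 (7 and 1 adjusted over the list alone, adjusted p = 0.00536, and adjusted p = 0.279 with an estimated correlation), with TGFA at 2.44 and a mean of -0.167 in BR6. Fibroblast markers moved with these lists, with PDGFRB the called gene of 7 (4 adjusted over the list alone, adjusted p = 0.0108, and adjusted p = 0.279 with an estimated correlation), at a mean of -0.015 in BR6. So did the 3 measured lymphocyte markers, with the interleukin receptor IL7R at least 7.58-fold higher and CD2 at 0.86 (2 adjusted over the list alone, adjusted p = 0.0339, and adjusted p = 0.2 with an estimated correlation).

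Pigmentation genes were lower in 18 of 31 cases (28 adjusted over the list alone, adjusted p = 1.59e-12, and adjusted p = 0.2 with an estimated correlation). Oxidative phosphorylation genes were lower in 15 of 37 cases (26 adjusted over the list alone, adjusted p = 3.11e-12, and adjusted p = 0.17 with an estimated correlation). Lysosomal genes were lower in 6 and higher in 1 of 27 (12 and 1 adjusted over the list alone, adjusted p = 0.00213, and adjusted p = 0.2 with an estimated correlation). Cholesterol biosynthesis genes were lower in 4 of 28 cases (4 adjusted over the list alone, adjusted p = 0.0023, and adjusted p = 0.372 with an estimated correlation), with DHCR7 at -1.15 and a mean of 0.113 in MR105.

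The on-drug difference called 2499 probes with limma, 1190 higher and 1309 lower, and of 1916 genes 1858 had the same sign in all 6 clones. Within the slides of the dabrafenib, combination and trametinib experiments, 99.9%, 100% and 100% kept the pooled direction. The untreated and on-drug differences called 312 genes in the same direction and 7 in opposite directions. They share no array but compare the same 9 lines, whose 2 arrays deviated together (r from 0.63 to 0.88), so an overlap is expected in any case. The count was 476, 667 and 1278 without the parental line of the trametinib, combination and dabrafenib experiment, 1528 without BR8, 1560 without MR201, and 425 without the experiment as a block. Of 27 called genes named here as largest or panel, 13 kept their call when any line was left out. Without the parental line of the trametinib experiment, 13 lost it, among them AXL (adjusted p = 0.103), MYC (0.0523), NGFR (0.065), SPRY4 (0.0689) and OCA2 (0.0635). Without that of the combination experiment, 11 lost it, among them AXL (0.099), CCNB1 (0.0714), CDKN1A (0.0655) and PPARGC1A (0.0701). Without that of the dabrafenib experiment, CCNB1 (0.0501) and PMEL (0.0671) lost it; without MR201, PDGFRB (0.0725), PMEL (0.06) and SPRY4 (0.053); and without BR8, CR401 or CR201, PDGFRB (0.0626, 0.0701 and 0.0676). The call was also lost with no filter on dim probes for AXL (0.0661), EGR1 (0.0556), PDGFRB (0.101), PMEL (0.0816) and SPRY4 (0.0772), with robust eBayes for AXL (0.06) and PMEL (0.0638), on the value table for PDGFRB (0.098) and PMEL (0.0529), at an offset of 100 for PDGFRB (0.0782) and SPRY4 (0.0721), and without a block for 8 genes.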

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

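The tests of a single clone, of keratinocytes, of fibroblasts and of lines exchanged within an experiment were chosen after the results they weigh were seen. So was the count of clones within their own slides. For keratinocytes and fibroblasts several rules were tried with the counts in view; the one used asks that more than 1 gene be absent from every untreated clone, and under a rule that asks for most of the genes the fibroblasts (3 of 6 genes, 7 of 14 over the whole list) stay undecided.

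Clones responded less to the inhibitors than parental cells: the response difference held 1758 probes, and 10 lists differed in their mean response by an exact permutation test (adjusted p = 0.0309 each, with no clone inside the parental range, but 0.0741 with lines exchanged only within an experiment). The differences, clone minus parental, were 1.07 for G1/S, 1.063 for G2/M, 0.754 for nucleolus, 0.713 for heat shock, 0.386 for the AXL-associated state, 0.129 for reference genes, -0.281 for oxidative phosphorylation, -0.384 for lysosome, -0.399 for CDK inhibitors and p53 targets and -0.541 for pigmentation. Dimmer treated parental arrays are argued against, since among the brightest genes the slope of the clone on the parental response was 0.4 (SD 0.15, n = 6, highest clone 0.6). Noise in the estimated parental response is argued against too, since the lowest slope of a held-out parental line was 0.81 and the highest of a clone 0.58. A biological difference between clones and parental cells may account for the pattern and stays a hypothesis, since it was found and tested on the same data.

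The BR clones on dabrafenib had fewer probes called than the CR and MR clones, and the test between sets called 2 probes for MR minus BR, TAGLN and NPPB. A weaker action of dabrafenib alone cannot be told apart from a property of these clones, since set, inhibitor and slide coincide. So may the parental line, as the labels name SK-Mel28 in that experiment and SK-Mel28#8 in the others, and the parental slope for dabrafenib of 0.81 lies within its spread of 0.07 from the bound of 0.8 set beforehand. That BR6 alone makes the difference is argued against for cell cycle genes, since BR8 stood at -0.128 in G2/M (CR and MR clones -0.554 to -0.723, SD 0.078) and at -0.156 in G1/S (-0.43 to -0.786, SD 0.153). Over all genes it stays open, since the slope of BR8 on the mean parental response, 0.3, lay below the lowest CR or MR clone, 0.34, by less than their SD of 0.12.

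Untreated clones had higher AXL-associated and lower pigmentation genes than parental cells, and BR6 lay far from the other clones. BR6 stood at 0.526 in the AXL-associated list (others 1.652 to 2.188), at -0.159 in receptor tyrosine kinases and ligands (0.796 or more) and at 0.322 in matrix and TGF-beta genes (1.049 to 1.474). Differences between slides are argued against, since 6 of 6 clones lay above the parental array of their own slide in the AXL-associated list and below it in the pigmentation list. Keratinocytes in the cultures are argued against for the lower pigmentation genes, and fibroblasts less firmly, since PMEL at -1.64 would need them to give most of the RNA, yet 4 of 6 keratins and 3 of 6 collagen and proteoglycan genes were above background on no untreated clone and LUM was lower (-0.86, SD 0.45); for the AXL-associated genes a small share stays open, since 2 of 6 measured keratinocyte and 4 of 7 fibroblast markers were higher by more than their SD, KRT17 and COL1A1 among them (above background on 5 of 6 clones and 0 of 3 parental arrays). A biological difference between clones and parental cells may account for it and stays untested.

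CR201 stood at 1.312 in the untreated difference of the endothelial markers, far from the other clones (-0.243 to 0.273). In all, 53 groups of 6 clones were examined for a distant clone, and chance alone marks about 1 in 20.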

How the results depend on the processing

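Leaving out the dabrafenib experiment and exchanging lines only within an experiment were chosen after seeing the data. No named gene or list that was called turned its direction in any alternative. The parental response was within 1.5 times its count of 7376 under each alternative except the change of at least 1 and the fit without a block. Asking for a larger change lowers counts by construction, and the cause of the other moves was not tested. Signal near background limits the folds of dim genes, and only bounds are given for these.

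Without background correction, the BR and CR responses had 190 and 2508 probes, CR minus BR 4, MR minus BR 4, MR minus CR 7, and the untreated BR and CR clones 11 and 18. Under median scaling, the response difference had 2647, MR minus BR 1, MR minus CR 6, the untreated difference 1747 and the untreated MR clones 128. On the deposited value table, the response difference had 1137, the BR, CR and MR responses 12, 1006 and 873, MR minus BR 0, the untreated difference 242, the on-drug difference 1624 and the untreated CR clones 51. With an offset of 100, the BR, CR and MR responses had about 2.0e2, 2828 and 2523, CR minus BR 13, MR minus BR 9, MR minus CR 6, and the untreated BR, CR and MR clones 11, 6 and 30. With no filter on dim probes, the BR and MR responses had 2 and 928, MR minus BR 0, the untreated difference 289, and the untreated BR, CR and MR clones 7, 13 and 16. With probes detected on every array, the BR response had 100, CR minus BR 1, MR minus BR 4, and the untreated BR, CR and MR clones 0, 0 and 16. With trended and robust eBayes, the BR, CR and MR responses had 285, 2748 and 2606, CR minus BR 12, MR minus BR 4 and MR minus CR 4. With array weights, the response difference had 2678, the BR, CR and MR responses 131, 2651 and 732, CR minus BR 1, MR minus BR 0, the untreated and on-drug differences 1538 and 4234, and the untreated BR, CR and MR clones 9053, 2843 and 5789.

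Without the replicate block, the parental and clone responses had 1635 and 152, their difference 45, the untreated and on-drug differences 95 and 425, the BR, CR and MR responses 2, 17 and 16, and MR minus BR 0, and the pigmentation list in the clone response had an adjusted p of 0.0746. At a change of at least 1, the 5 main comparisons had 2337, 397, 779, 423 and 1314. Against their own parental array, the untreated BR, CR and MR clones had 0, 5 and 6. Without the dabrafenib experiment, the response difference had 572. With lines exchanged only within an experiment, 16 list outcomes of the permutation test were the same and 10 lost the call (adjusted p = 0.0741). With an estimated correlation, the lists of MAPK output, G1/S, G2/M and pigmentation had adjusted p = 0.092, 0.113, 0.169 and 0.169 in the parental response, 0.139, 0.2, 0.271 and 0.342 in the clone response, and 0.276, 0.129, 0.204 and 0.211 in the difference.

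Leaving out each line in turn gave 5247 to 7508 probes for the parental response, 2662 to 4406 for the clone response, 555 to 1829 for their difference, 0 to 32, 90 to 1920 and 7 to 1796 for the BR, CR and MR responses, and 0 to 1 for MR minus BR. It gave 40 to 1468 for the untreated and 476 to 3186 for the on-drug difference, and 0 to 5445, 0 to 287 and 2 to 180 for the untreated BR, CR and MR clones. Of the named genes under these settings, 4436 outcomes were the same, 51 were newly called and 436 lost the call; of the lists, 1140 were the same, 11 were newly called and 19 lost it. With fry in place of camera, 102 lists were the same, 18 were newly called and 10 lost it: interferon in the clone response, receptor tyrosine kinases, glycolysis, cholesterol and matrix in the untreated (adjusted p = 0.146, 0.0865, 0.0866 and 0.0504) and on-drug differences (0.0604, 0.0694, 0.0945 and 0.0636), and fibroblast markers in the latter (0.0664).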

Other observations

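The correlations among genes that differ by more than 0.5, 1 or 2 were added after the one over all genes was seen; release of the pathway over all genes and the splits of the samples were set beforehand.

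Interferon response genes were higher in untreated clones in 11 of 34 cases (19, and 1 lower, adjusted over the list alone, adjusted p = 5.27e-09, and adjusted p = 0.121 with an estimated correlation). They included the antiviral genes GBP1 at 1.51 ± 0.4 and IFIT1 at 1.69 ± 0.75 (SD, n = 6). On inhibitor, 13 were higher and 1 lower (20 and 2 adjusted over the list alone, adjusted p = 3.73e-07, and adjusted p = 0.145 with an estimated correlation), with OAS2 at 2.3 ± 0.95 (SD, n = 6). Inhibitor raised 11 of them and lowered 1 in the clones (11 and 1 adjusted over the list alone, adjusted p = 0.0089, and adjusted p = 0.523 with an estimated correlation), which fry did not call (adjusted p = 0.0805); the list's mean was 0.558 in CR401, 0.644 in CR201, 0.146 in BR6, 0.239 in BR8, 0.069 in MR201 and -0.191 in MR105. Antigen presentation genes were higher in untreated clones in 2 of 15 cases (7 adjusted over the list alone, adjusted p = 0.000259, and adjusted p = 0.172 with an estimated correlation), the peptide transporter TAP1 at 1 and HLA-B at 2.2.

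Glycolysis and hypoxia genes were higher in untreated clones in 4 of 30 cases (7 adjusted over the list alone, adjusted p = 0.00102, and adjusted p = 0.322 with an estimated correlation), with the growth factor VEGFA at 1.97 ± 0.72 and the glucose transporter SLC2A1 at 1.47 ± 0.63 (SD, n = 6). Inhibitor lowered 6 of them in the clones (6 adjusted over the list alone, adjusted p = 0.00233, and adjusted p = 0.158 with an estimated correlation). Among them was VEGFA at -1.2. Genes of ATF4 and the unfolded protein response were higher in untreated clones in 5 of 28 cases (8 adjusted over the list alone, adjusted p = 9.63e-05, and adjusted p = 0.268 with an estimated correlation), with DDIT3 at 1.3 and PPP1R15A at 1.07. In the clone response 10 fell and 1 rose (13 and 2 adjusted over the list alone, adjusted p = 0.00116, and adjusted p = 0.2 with an estimated correlation). Among them was TRIB3 at -1.07.

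The markers of keratinocytes, macrophages and endothelium were not called by camera in the untreated difference (adjusted p = 0.224, 0.735 and 0.623 over 6, 6 and 4 measured genes). On inhibitor, 2 keratinocyte markers were higher (2 adjusted over the list alone, adjusted p = 0.069 with camera and 0.00429 with fry), PERP at 1.07 and KRT17 at least 4.97-fold. The endothelial markers had 1 lower gene there, VWF at -1.52, and their mean (-0.0645) and median (0.3956) differ in sign.

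A hypothesis was that release of the pathway in clones without inhibitor shapes the genes that differ between untreated clones and untreated parental cells, which may give a negative correlation with the parental response to inhibitor. Pearson r across 14873 genes between the untreated difference of an experiment and the parental response of the other 2 was 0.05, 0.02 and 0 for the dabrafenib, combination and trametinib experiments. The highest was 0.05 and none was under the -0.2 set beforehand, and among genes differing by more than 0.5, 1 or 2 in that experiment the lowest r was -0.14. Release as the cause of most of these genes is argued against. It stays open for the MAPK output and immediate early lists, which were higher in untreated clones (adjusted p = 1.41e-05 and 5.46e-09, but 0.172 and 0.121 with an estimated correlation), although DUSP6 (0.32) and SPRY2 (-0.1) did not pass.

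Other splits of the samples were fitted for the main comparisons. For the clone response, 1 of 98 splits of the 12 arrays, the real one, called as many probes (4302), and the highest other called 3468; 2 of 100 drawn could not be fitted, and of the 32 splits that part all 6 pairs the highest other called 41. For the response difference, 1 of 84 splits of the 9 lines called as many (1758, highest other 0). For the untreated difference it was 1 of 81 (670, highest other 47) and for the on-drug difference 1 of 81 (2499, highest other 4). A regrouped split carries the real difference into its spread, so low counts there are partly built in. In the last 3 comparisons, 27 splits each take 1 line per experiment as the real one does, so the smallest possible share is 0.037. The 4 counts exceed those of the other splits, which does not exclude chance. The 10 splits of the 6 parental arrays are too few for a share under 0.05: the real one called 7376 and the highest other 0.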
